A study of Rattus norvegicus with 14 samples.

How the data were processed

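The series held 14 RNA libraries from dorsal root ganglia L2 to L5 of 7 male rats, with a control and a surgical library for each rat. The group, rat and time of each library were taken from the sample titles and the column names. Letters C and D were exchanged between the titles and the library names on both sides, which left every pair of libraries intact, and the title letters were used. The title of the surgical library of rat C called it replicate 1, and it was used as replicate 2. Per the labels the extracted molecule was polyA RNA, while the extraction protocol in the same labels named ribosomal depletion with an NEB kit; both statements are given as found.

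The authors deposited estimated counts and TPM per gene. Per the submitters' processing notes, reads were checked with FastQC, trimmed with Trim Galore and quantified with Salmon, and DESeq2 was used for expression analysis; the notes gave no version and no genome build. The deposited estimated counts, made by the authors with Salmon, were whole numbers (0 non-whole values), and the deposited TPM were made by the authors from the same quantification. The tables held 30562 Ensembl genes, 4367 of them without a symbol and 544 with a symbol shared by several genes, and 682 cells had a count of 0 with a TPM above 0. Genes were named by the symbols in the files, and where there was none by the Ensembl identifier. The ratio of count to TPM gave a relative transcript length for each gene, which was used for the length checks on genes with at least 20 counts in 3 libraries.

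The estimated counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, libraries were scaled by TMM, and a quasi-likelihood model was fitted with robust dispersion. P values were two-sided, and genes passed at an adjusted p under 0.05 after Benjamini-Hochberg adjustment over all genes tested in a comparison. The 6 comparisons were surgical against control over both times, the same at 6 weeks and at 8 weeks, the difference between those changes, and 8 against 6 weeks on the control side and on the surgical side. The comparisons of the sides held the rat as a block over all 14 libraries, with 6 residual degrees of freedom over both times and 5 at each time. The comparisons of the times were between different rats, with 5 residual degrees of freedom. Log2 differences came from the fitted model, and the SE of each was its size divided by the square root of the quasi-likelihood F. Levels in single libraries were log2 CPM with a prior count of 2. A fold against a group with 0 counts was given as a lower bound against 3 counts in each library.

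The design, the samples of each comparison, the gene lists and most alternative settings were fixed before the data were examined. Alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter and a stricter filter at 1 CPM, no robust dispersion, no block, a block with rats C and D crossed, only the libraries of 1 time, and limma 3.58.1 on log2 TPM with 1 or 0.1 added for genes with at least 0.5 TPM. Each rat was also left out in turn. Later alternatives were the removal of rats B, C and H together, the removal of rats A and B, and the mean level of 16 neuronal markers as a covariate. Another removed a lowess trend (span 0.3) with transcript length in each library, fitted to log2 CPM less the mean of each gene. Library measures were compared by exact sign flips over rats or exact splits of the libraries. The number of genes called was compared with that of other splits of the libraries of the same sizes, all of them or, over both times, a random 99 beside the real one.

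Lists of genes were chosen for 27 cell types and programmes: axon injury and regeneration, peptidergic nociceptors, non-peptidergic nociceptors and pruriceptors, cold receptors and C-LTMR, proprioceptors and myelinated mechanoreceptors, potassium channels, sodium and calcium channels, opioid, GABA and other inhibitory receptors, and neurotrophic factors and receptors. The others were satellite glia, myelinating Schwann cells, repair Schwann cells, macrophages, MHC class II and interferon response, T, B and NK cells, neutrophils, inflammatory cytokines and chemokines, red blood cells, endothelial cells and pericytes, fibroblasts and collagens, skeletal muscle, adipocytes, spinal cord and central glia, immediate early genes, circadian clock, glucocorticoid response and cholesterol synthesis. They held 506 entries, of which 16 were not in the tables, among them Mrgprx2, Kcnb2, Cd4, Trbc1, Trac, Hba-a2, Hbb-bs, Hbb-b1, Cldn5, Myh1, Mylpf, Dusp1, Arntl and Mt2. Lists with at least 5 tested genes were tested by camera with a preset correlation of 0.01 between genes, by camera with an estimated correlation and by fry, adjusted over the lists of a comparison. The level of a list in a library was the mean log2 CPM of its genes.

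Single genes were named by rule. Among genes past the threshold with a symbol and a mean of at least 1 TPM in either group, and changed the same way in every rat where the sides were compared, the 12 largest rises and the 12 largest falls were named. Where none passed, the 3 genes with the smallest p in each direction were named as values that did not pass. To these were added up to 4 genes with the smallest p of each list, and in the comparison over both times 20 genes chosen beforehand, among them Atf3, Sprr1a, Gal, Npy, Vip, Gap43, Csf1, Sox11, Calca, Tac1, Trpv1, Scn10a, Mrgprd, P2rx3, Pvalb, Runx3, Nefh, Cd68 and Acta1. Some genes that the rule covers are not reported here. Other genes are stated as named after their values were seen.

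The pairing of libraries was checked by correlating, over genes, the deviations of both libraries of a rat from their group means. The correlations were 0.26 in rat A, -0.121 in B, 0.75 in E, -0.0855 in D, -0.409 in C, 0.128 in G and -0.308 in H, against 0.371 for control C with surgical D and 0.0552 for control D with surgical C. Only 2 control libraries matched the surgical library of their own rat best, so the files could not settle the exchange of letters, and the block is taken from the titles. Replicate libraries of a group correlated at 0.879 to 0.983, and the first principal component held 45.5% of the variance. In a self-test, 200 changed genes were placed in simulated counts of each comparison with the fitted dispersion, 100 at each of 2-fold and 4-fold. Over both times 4 of 128 calls (3.12%) were unchanged genes, and in the control comparison 5 of 88; at a smaller dispersion, 0.1 of the fitted, the recovery at 2-fold was 99% and 96%.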

Results

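Dorsal root ganglia hold the cell bodies of the sensory neurons that serve a limb, together with their glia, vessels and resident immune cells. RNA was sequenced from lumbar ganglia of 7 male rats in which a free muscle graft had been joined to the saphenous nerve, a sensory nerve of the leg, in one hindlimb. The other hindlimb of each rat was not operated on and served as its control. Rats A, B and E were sampled 6 weeks after the operation and rats D, C, G and H at 8 weeks, so the 14 libraries formed 4 groups of 3 control and 3 surgical libraries at 6 weeks and 4 of each at 8 weeks. The total estimated counts at 6 weeks were 19796261 in the control and 19703406 in the surgical library of rat A, 20146390 and 20561475 in rat B, and 21029173 and 18489118 in rat E. At 8 weeks they were 28237574 in the control and 22633941 in the surgical library of rat D, 21590793 and 24540896 in rat C, 27717035 and 24387703 in rat G, and 21972609 and 23374217 in rat H. Values below are log2 differences with their standard error (SE), or mean TPM with their standard deviation (SD) over the rats of a group. CPM stands for counts scaled to the size of each library.

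The libraries differed widely in tissue content. The mean log2 CPM of 16 neuronal marker genes was 8.13 (SD 0.81, n = 3) in control and 8.02 (SD 1.23, n = 3) in surgical ganglia at 6 weeks, and 9.05 (SD 0.25, n = 4) and 8.87 (SD 0.49, n = 4) at 8 weeks. The lowest neuronal levels were 6.62 in the surgical library of rat A and 7.32 in the control library of rat B. Skeletal muscle genes reached 10.38 in the surgical library of rat C, 8.33 in the control library of rat H and 5.91 in the surgical library of rat E, against a mean of 1.75 (SD 0.92) in the other 11 libraries. Spinal cord and central glia genes reached 6.05 in the surgical library of rat B and 1.25 in its control. Haemoglobin transcripts took from 26630 to 163000 TPM of a library and mitochondrial transcripts from 118500 to 308400 TPM. The neuronal level differed between the sides by -0.16 (SD 0.91, n = 7; two-sided exact sign flip p = 0.656, adjusted p = 0.656 over 5 library measures, where the smallest p the design allows is 0.0156). On the control side the values at 8 and 6 weeks did not pass a test (two-sided exact permutation p = 0.0571, adjusted p = 0.143). The log2 CPM of each gene, less its mean over all libraries, was also correlated with transcript length across genes. This correlation averaged -0.20 (SD 0.02, n = 3) in the 6-week controls and 0.07 (SD 0.07, n = 4) in the 8-week controls (exact permutation p = 0.0286, the smallest the split allows, adjusted p = 0.143). Its sign is relative to the average of these libraries. Genes are not independent replicates, and the contrast is between libraries.

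**Figure D1:**
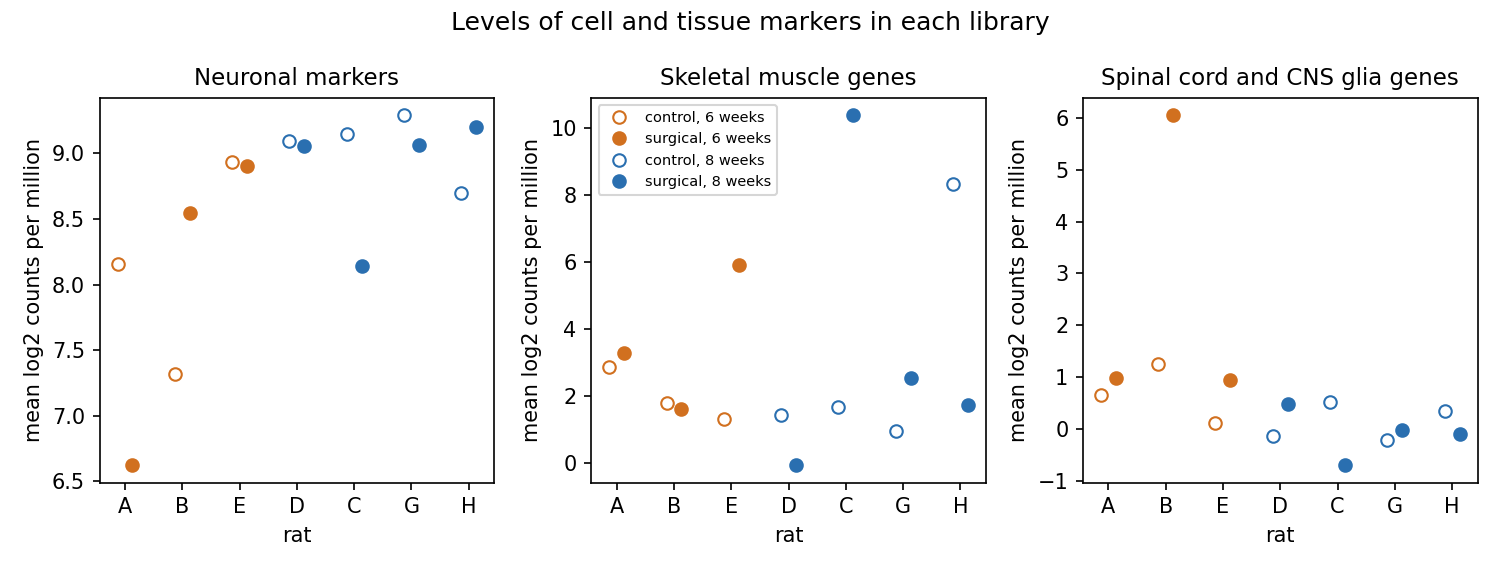
Mean log2 CPM of neuronal markers, skeletal muscle genes and spinal cord genes in each library, 1 point per library, by rat, with open points for control and filled points for surgical ganglia. Skeletal muscle genes stand at 10.38 in the surgical library of rat C and spinal cord genes at 6.05 in the surgical library of rat B.

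The first comparison asked which transcripts differ in ganglia whose nerve was given muscle as a new target, with both times together and each rat as its own control. Vip (ENSRNOG00000018808), a neuropeptide gene that sensory neurons express after their axons are severed, averaged 3.83 TPM (SD 2.66, n = 7) in surgical and 0.179 TPM (SD 0.137, n = 7) in control ganglia, a log2 difference of 4.05 (SE 0.94; higher in 6 of 7 rats). Stac2 (ENSRNOG00000004805), whose product binds voltage-gated calcium channels, averaged 4.57 TPM (SD 4.29, n = 7) against 0.297 (SD 0.09, n = 7), a log2 difference of 3.36 (SE 0.61; higher in 7 of 7 rats). Gal, the galanin neuropeptide gene, averaged 40.6 TPM (SD 17.1, n = 7) against 17.3 (SD 8.16, n = 7), a log2 difference of 1.21 (SE 0.42; higher in 6 of 7 rats). On the other side of 0, Rgs10, a regulator of G-protein signalling, had a log2 difference of -0.65 (SE 0.13), Fxyd2, a sodium pump subunit gene of nociceptors, -0.71 (SE 0.17), and C10h17orf67 -1.56 (SE 0.37), and each of these was higher on the surgical side in 0 of 7 rats. None of these differences passed the test (adjusted p = 1 for each, edgeR quasi-likelihood with Benjamini-Hochberg adjustment): 0 of 17035 genes did, and 412 had an unadjusted p under 0.05. DESeq2 called 6 genes on the same counts, namely Stac2, Vip and Pde6b higher and Rgs10, Pcbd1 and LOC120099694 lower, of which Pde6b, Pcbd1 and LOC120099694 are named here after their values were seen. limma on log2 TPM called 0 with either added constant. In simulated data with the dispersion fitted to these libraries the edgeR test recovered 35% of genes changed 2-fold and 89% of genes changed 4-fold. The simulation left out rat effects, drew each gene independently and changed only genes with a mean above 1 CPM. Differences in tissue content shared across genes were therefore not simulated, and recovery in the real libraries could be lower. The same holds for the recoveries given below.

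The genes chosen beforehand for this comparison showed the following values, none past the threshold (adjusted p = 1 for each, edgeR, n = 7 rats). The transcription factor genes of the axon injury response, Atf3 and Sox11, had log2 differences of 0.75 (SE 0.35; higher in 5 of 7 rats) and 0.82 (SE 0.28; 6 of 7 rats). The growth cone gene Gap43 stood at -0.10 (SE 0.26), the microglia-recruiting cytokine gene Csf1 at 0.15 (SE 0.21), and the neuropeptide gene Npy at -0.78 (SE 0.33; higher in 1 of 7 rats). Sprr1a, another axon injury gene, was not tested, since its highest count in any library was 20. Markers of peptidergic nociceptors lay on the negative side of 0, with Calca at -0.40 (SE 0.31), Tac1 at -0.57 (SE 0.37) and the heat receptor gene Trpv1 at -0.35 (SE 0.35), as did the nociceptor sodium channel gene Scn10a at -0.24 (SE 0.44). The non-peptidergic markers Mrgprd and P2rx3 stood at -0.73 (SE 0.39) and -0.55 (SE 0.42), each higher in 2 of 7 rats. Genes of proprioceptors and large myelinated neurons were near 0, with Pvalb at 0.23 (SE 0.41), Runx3 at 0.14 (SE 0.19) and Nefh at -0.00 (SE 0.34), the last of which changed sign with the scaling. The macrophage gene Cd68 stood at 0.29 (SE 0.50) and the muscle actin gene Acta1 at 0.86 (SE 1.63). Without rat C the values of Cd68 (-0.12, SE 0.26), Pvalb (-0.13, SE 0.21), Csf1 (-0.05, SE 0.12) and Gap43 (0.09, SE 0.22) changed sign, as did those of Scn10a (0.09, SE 0.36) without rat A and Runx3 (-0.12, SE 0.18) without rats B, C and H. Of genes not chosen beforehand and named after the fit, Cacna2d1, a calcium channel subunit gene and the target of gabapentin, stood at 0.67 (SE 0.35; higher in 6 of 7 rats). Ssc5d, a secreted scavenger receptor gene likewise named after the fit, stood at 0.61 (SE 0.15; higher in 7 of 7 rats).

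**Figure D2:**
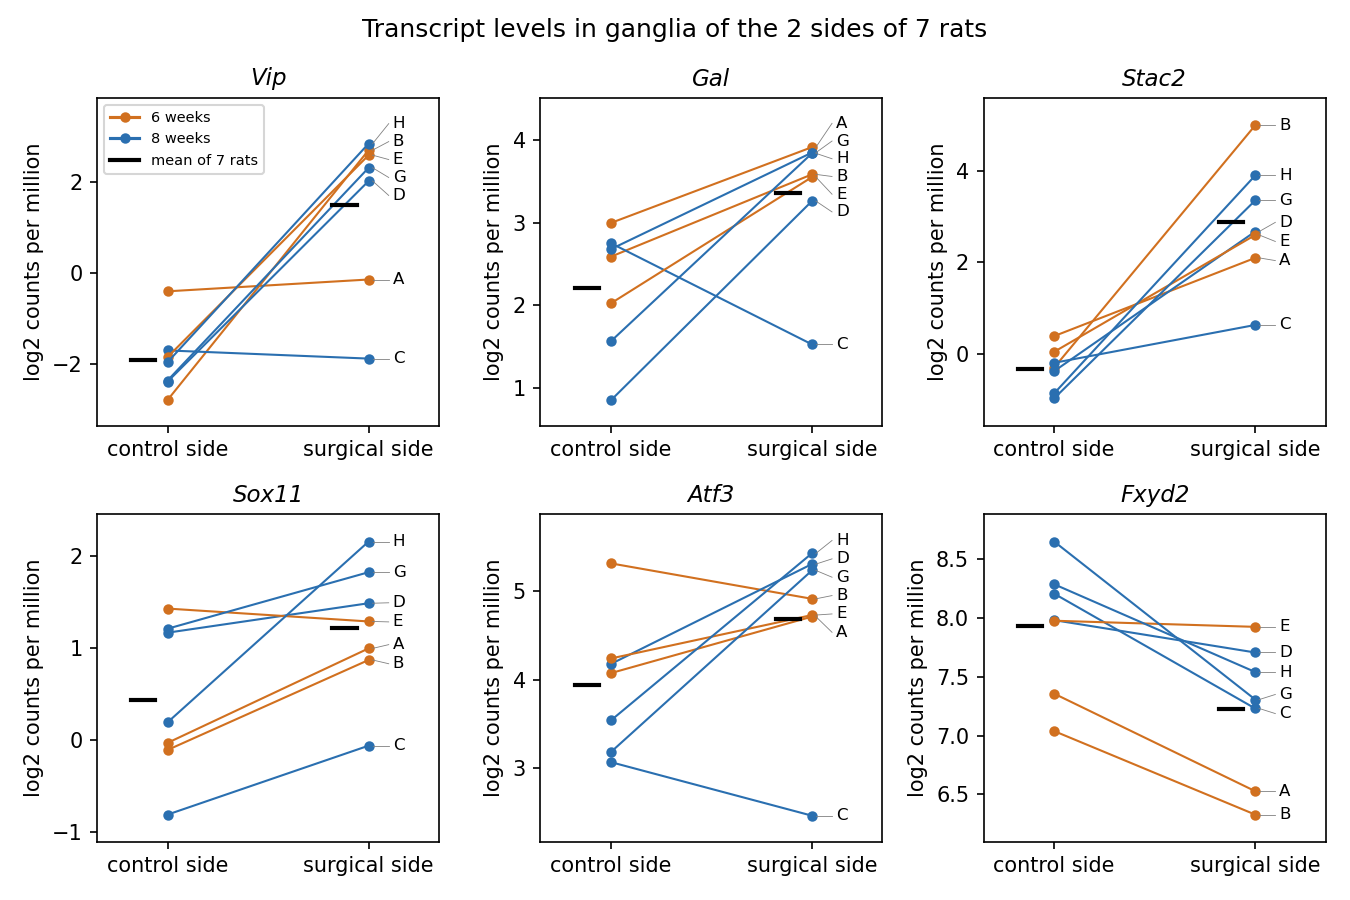
Log2 CPM of Vip, Gal, Stac2, Sox11, Atf3 and Fxyd2 on the control and surgical side, with a line per rat, colour for the time and a bar for the mean of 7 rats. Vip lies higher on the surgical side in 6 of 7 rats, with rat C below its own control.

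As a group, the axon injury and regeneration genes lay higher on the surgical side: 23 of 30 had a positive log2 difference, with a median of 0.20 and a mean of 0.45. The non-peptidergic nociceptor and pruriceptor genes lay lower, with 14 of 15 negative and a median of -0.58. Their lists passed camera with its preset correlation (Up, adjusted p = 9.46e-06, higher in 5 of 7 rats, and Down, adjusted p = 2.41e-08, higher in 2 of 7 rats). Neither held when the correlation between genes was estimated (adjusted p = 0.703 with an estimated correlation for both). With the neuronal marker level as a covariate, chosen after the data were seen, the axon injury list passed (adjusted p = 0.0292 with an estimated correlation, and 0.0151 by fry) and the non-peptidergic list did not (0.677 and 0.439). With the preset correlation and without that covariate 4 more lists were Up, those of neutrophil genes (median 0.60, adjusted p = 0.000698), spinal cord and central glia genes (0.98, 0.000699), red blood cell genes (0.53, 0.0082) and skeletal muscle genes (0.86, 0.0188), and 3 were Down, those of cholesterol synthesis genes (-0.16, 0.0134), peptidergic nociceptor genes (-0.19, 0.0188) and adipocyte genes (-0.41, 0.0447). Each of these 7 had adjusted p = 0.942 with an estimated correlation. With the covariate 4 of the 7 had adjusted p above 0.05 with the preset correlation as well, those of red blood cell (0.0704), muscle (0.264), cholesterol synthesis (0.101) and peptidergic genes (0.0704). fry, which asks whether the genes of a list move one way on balance, called 0 of 27 lists (smallest adjusted p = 0.812). No list held a gene past the threshold over all genes tested, nor any adjusted over the list alone.

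The 2 lists named first kept their calls without each rat in turn, and the other 7 each rested on single rats. Without rat B the spinal cord list had an adjusted p of 0.37 and the adipocyte list of 0.25. Without rat C the muscle list turned to Down (0.776), the cholesterol list to Up (0.583), and the peptidergic (0.441), red blood cell (0.388) and neutrophil lists (0.177) no longer passed. Without rat G 6 calls were lost, those of the adipocyte (0.716), red blood cell (0.277), neutrophil (0.134), peptidergic (0.132), muscle (0.132) and cholesterol lists (0.111). The peptidergic call was also lost without rat A (0.32), the muscle call without rat E (0.544) and the adipocyte call without rat H (0.122).

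The other 18 lists did not pass camera with the preset correlation over both times, and none passed with an estimated one. Cold receptor and C-LTMR genes, which mark cool-sensing and gentle-touch neurons, had a median of -0.14 (adjusted p = 0.0833), proprioceptor and myelinated mechanoreceptor genes -0.02 (0.808), and neurotrophic factor and receptor genes -0.11 (0.194). Among channel and receptor genes the medians were -0.12 for potassium channels (0.121), -0.05 for sodium and calcium channels (0.959) and -0.04 for opioid, GABA and other inhibitory receptors (0.335). Glial lists stood at -0.05 for satellite glia (0.875), -0.10 for myelinating Schwann cells (0.513) and 0.06 for repair Schwann cells (0.475). Without rats B, C and H, a choice made after the data were seen, the myelinating Schwann cell list turned from Down to Up (adjusted p = 1.5e-16; adjusted p = 0.565 with an estimated correlation), as it did at 8 weeks, where 2 rats were left (2.32e-16; 0.85 with an estimated correlation). Immune lists stood at 0.15 for macrophages (0.228), -0.06 for MHC class II and interferon response genes (0.491), 0.19 for T, B and NK cells (0.111) and -0.28 for inflammatory cytokines and chemokines (0.0812). Without rats B, C and H the MHC class II and interferon (0.0231), fibroblast (0.0107) and immediate early lists (0.0108) also turned from Down to Up, with adjusted p of 0.565, 0.628 and 0.565 with an estimated correlation. With the neuronal covariate at 6 weeks these lists instead passed as Down with the preset correlation (adjusted p = 8.75e-08, 0.0182 and 0.0194). With an estimated correlation they did not (0.199, 0.763 and 0.705), and at 8 weeks with that covariate none of them passed. Over both times the MHC class II and interferon median changed sign once the trend with transcript length was removed (0.02 relative to all genes). Endothelial and pericyte genes stood at -0.03 (0.513) and fibroblast and collagen genes at -0.16 (0.194). Immediate early genes stood at -0.08 (0.512), circadian clock genes at -0.03 (0.835) and glucocorticoid response genes at 0.04 (0.491). Median, mean and test differed in sign for sodium and calcium channels (mean 0.01, Down), circadian clock genes (mean 0.02, Down) and glucocorticoid response genes (mean -0.07, Down).

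**Figure D3:**
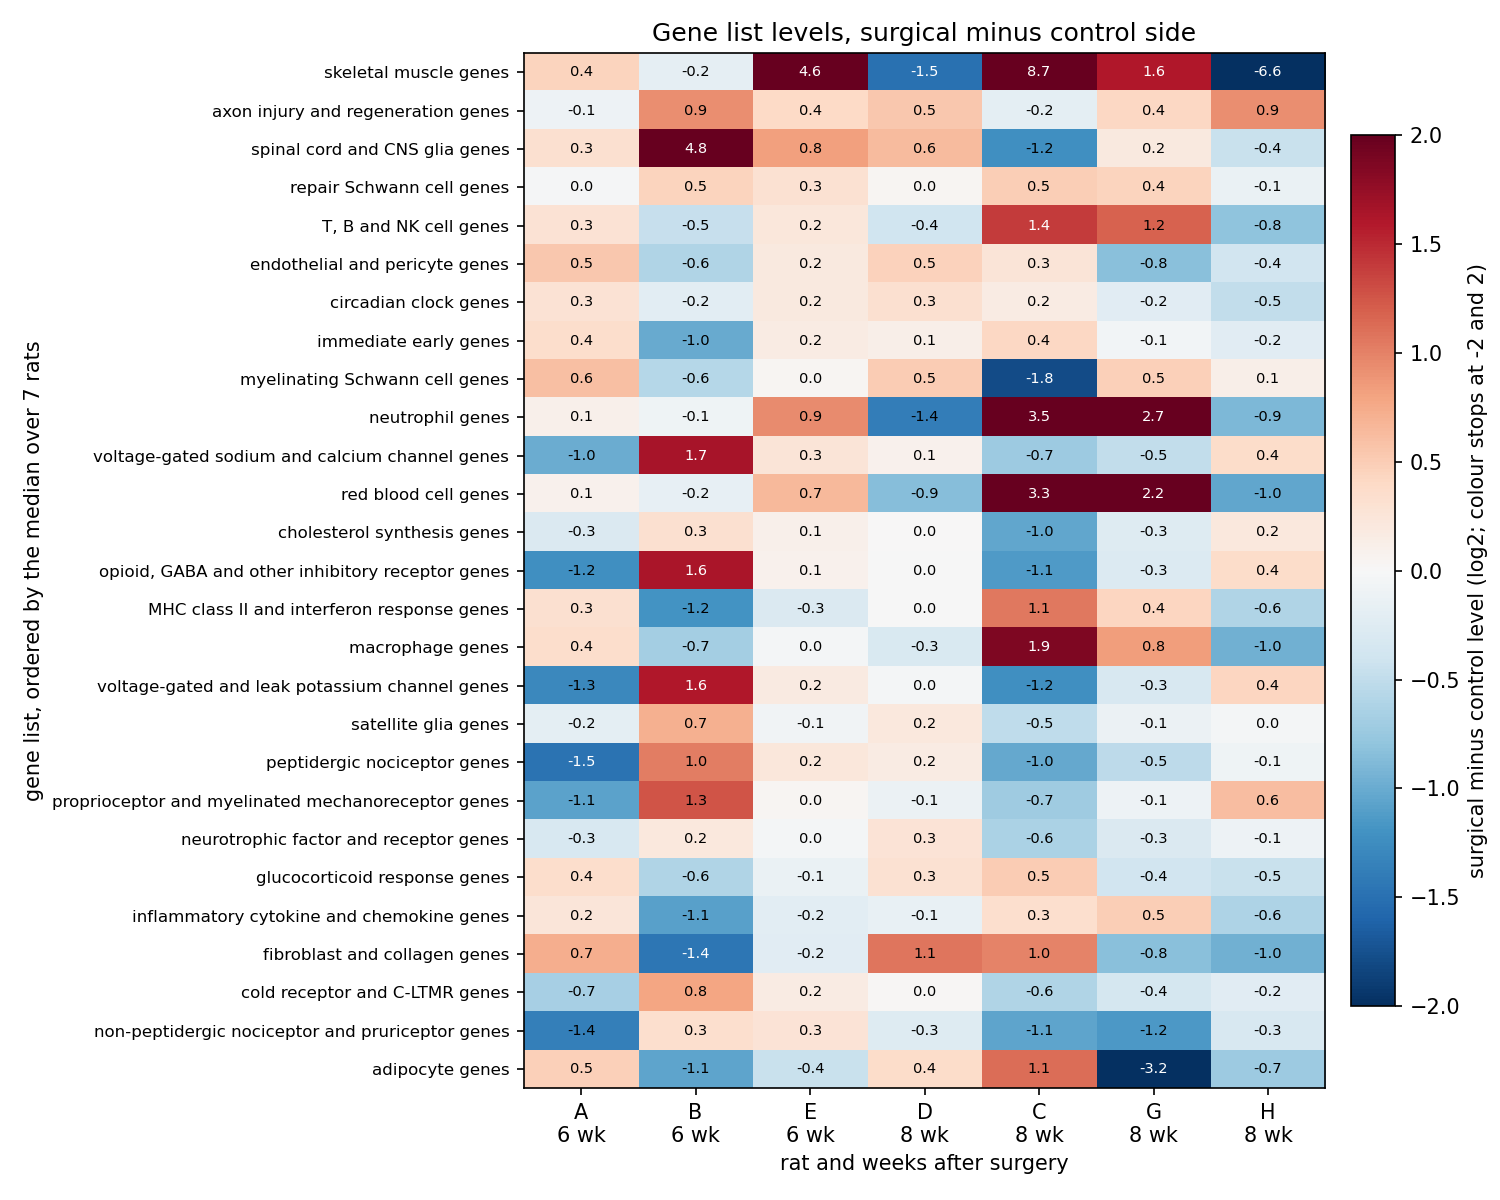
Surgical minus control level (mean log2 CPM) of each gene list in each rat, with lists ordered by their median over 7 rats and colour stopping at -2 and 2. Axon injury genes are higher on the surgical side in 5 of 7 rats, and rat C stands apart in the muscle list at 8.7.

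At 6 weeks, the earlier time after grafting, the naming rule gave 3 mitochondrial genes among those lower on the surgical side. Slirp, which encodes a stabiliser of mitochondrial mRNA, averaged 69.8 TPM (SD 19.8, n = 3) in surgical and 125 TPM (SD 33.6, n = 3) in control ganglia, a log2 difference of -1.07 (SE 0.15; higher in 0 of 3 rats). The mitochondrial import gene Timm8b stood at -1.05 (SE 0.15) and Cox7b, a subunit gene of cytochrome oxidase, at -1.22 (SE 0.19), both higher in 0 of 3 rats. Ddx6, an RNA helicase gene, stood at 0.66 (SE 0.16; higher in 3 of 3 rats). Slirp, Timm8b and Cox7b lie at the 2.5, 1.94 and 1.84 percentiles of transcript length, and across genes the log2 difference at 6 weeks was larger for longer transcripts (Spearman 0.405 over 15910 genes, which are not independent replicates). All 3 were also higher in the 6-week than in the 8-week controls, so their low values need not come from the surgical side. Arxes1 and Rpl39-ps10 had the smallest p values among higher genes beside Ddx6, yet were counted on the surgical side of 1 rat only, with 39 counts in rat B and 140 counts in rat E. None of these passed the test (adjusted p = 0.999, edgeR): 0 of 17035 genes did and 546 had an unadjusted p under 0.05, limma called 0, and DESeq2 called 44 (5 higher, 39 lower). The 5 higher ones were Ddx6, Slc32a1, Stac2, Soga1 and Rn5-8s, of which the last 3 are named after their values were seen. Without the rat as a block edgeR called 2 genes, Slirp and Timm8b, both lower. The simulated data gave recoveries of 1% at 2-fold and 41% at 4-fold.

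Spinal cord genes set the strongest list result at 6 weeks, with all 13 tested genes positive and a median of 2.36 (camera preset, Up, adjusted p = 6.4e-13, higher in 3 of 3 rats; adjusted p = 0.977 with an estimated correlation). The inhibitory transporter gene Slc32a1 stood at 3.27 (SE 0.86) and the oligodendrocyte gene Mog at 2.98 (SE 0.89), mostly from rat B. Axon injury genes were Up with 20 of 30 positive, a median of 0.25 and a mean of 0.43 (adjusted p = 0.00887, higher in 2 of 3 rats, adjusted p = 0.977 with an estimated correlation). By rat the level of that list differed by -0.103 in A, 0.932 in B and 0.396 in E. Rat B, whose surgical library had the high spinal cord level, thus gave the largest part. Muscle genes (median 1.45, adjusted p = 0.00319) and sodium and calcium channels (0.34, 0.0137) were also Up, and MHC class II and interferon genes (-0.35, 0.000984) and inflammatory cytokines (-0.40, 0.0137) were Down. For these lists too, adjusted p = 0.977 with an estimated correlation, and fry called 0 (smallest adjusted p = 0.983). Without rat B the sodium and calcium channel list passed in the other direction (Down, adjusted p = 0.0249), the MHC list had 0.369 and the cytokine list 0.56, both then Up. These values are from camera with the preset correlation, and none with an estimated one is given for that fit. Without rat E the muscle list had an adjusted p of 0.851. Only the spinal cord and axon injury lists kept their calls with the preset correlation without each rat in turn. Median and test differed in sign for peptidergic nociceptor genes (median 0.05, mean -0.03, Down) and for myelinating Schwann cell genes (median -0.06, mean 0.03, Up). Neurotrophic factor genes had a median of -0.00 and a mean of -0.05 with the test Up, and their median changed sign with the scaling.

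At 8 weeks, the later time, the naming rule gave the homeobox genes Hoxd10 and Hoxd11 and the gene Pde6b among those higher on the surgical side. Hoxd10, a gene of lumbar body position, averaged 2.65 TPM (SD 2.01, n = 4) against 0.322 (SD 0.208, n = 4), a log2 difference of 3.00 (SE 0.66), and Hoxd11 stood at 4.10 (SE 0.94), each higher in 4 of 4 rats. Pde6b, a phosphodiesterase gene, stood at 3.33 (SE 0.80; 4 of 4 rats), Vip at 4.27 (SE 1.33; 3 of 4 rats) and Gadd45a, a stress response gene, at 0.56 (SE 0.15; 4 of 4 rats). Atf3 stood at 1.16 (SE 0.45; higher in 3 of 4 rats). Skap1, a T cell adaptor gene, stood at -1.12 (SE 0.28), the carboxypeptidase gene Cpm at -0.78 (SE 0.20) and Fxyd2 at -0.84 (SE 0.22), each higher in 0 of 4 rats. None passed the test (adjusted p = 1, edgeR): 0 of 17035 genes did, 180 had an unadjusted p under 0.05, limma called 0, and DESeq2 called 4, all higher. These were Hoxd10, Stac2, Hoxc11 and Mmp3, the last 3 named after their values were seen. The simulated data gave recoveries of 7% at 2-fold and 64% at 4-fold.

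Non-peptidergic nociceptor and pruriceptor genes were the lowest neuronal group at 8 weeks, with 14 of 15 negative, a median of -0.74 (camera preset, Down, adjusted p = 6.82e-13, higher in 0 of 4 rats; adjusted p = 0.779 with an estimated correlation). Its members Mrgprx3 (-0.996, SE 0.32), Gfra2 (-0.72, SE 0.27) and Lpar3 (-1.03, SE 0.43) each had an adjusted p of 0.139 over the list alone. Cold receptor and C-LTMR genes had a median of -0.43 (Down, adjusted p = 0.00155, higher in 1 of 4 rats; adjusted p = 0.779 with an estimated correlation), with P2ry1 at -0.51 (SE 0.15) and Tafa4 at -0.96 (SE 0.41). Axon injury genes had 21 of 30 positive, a median of 0.17 and a mean of 0.47 (Up, adjusted p = 0.000176, higher in 3 of 4 rats; adjusted p = 0.779 with an estimated correlation). Without rat H that list had an adjusted p of 0.356. In all, 6 lists were Up and 9 Down with the preset correlation, 0 with an estimated one (smallest adjusted p = 0.779), and 0 by fry (smallest adjusted p = 0.995). Only the non-peptidergic and the cold receptor lists kept their calls without each rat in turn. Without rat C 11 calls were lost (adjusted p from 0.1 to 0.951, 5 with the direction changed), without rat G 8 (0.125 to 0.921, 2 with the direction changed) and without rat H 2 (0.214 to 0.356). Those resting on rat C included cholesterol synthesis (median -0.26, adjusted p = 3.63e-06, 0.951 without it), neutrophil (0.96, 0.000179, then 0.72), peptidergic nociceptor (-0.40, 0.000409, then 0.224) and potassium channel genes (-0.21, 0.000418, then 0.893). Median and mean differed in sign for muscle genes (-0.01 and 0.22, Up), fibroblast genes (0.13 and -0.00, Down) and spinal cord genes (0.03 and -0.15, Down), and the muscle and cytokine medians changed sign with the scaling.

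Whether the change on the surgical side itself differed between the times was tested as the 8-week change minus the 6-week change. Slirp had a difference of 1.03 (SE 0.19), Timm8b of 0.96 (SE 0.19) and Cox7b of 1.14 (SE 0.25), from the lower surgical minus control values at 6 weeks. In the controls alone the same 3 genes were lower at 8 than at 6 weeks, by -1.10, -1.15 and -1.47. The difference therefore does not by itself show a fall on the surgical side. Across genes it was smaller for longer transcripts (Spearman -0.36 over 15910 genes, which are not independent replicates). Cpne3, a calcium-dependent membrane-binding protein gene, had -0.89 (SE 0.24), and Arxes1 and Rpl39-ps10 were also among the smallest p values, since they were absent from the 6-week controls. None passed (adjusted p = 1, edgeR, 7 rats): 0 of 17035 genes did, 252 had an unadjusted p under 0.05, limma called 0, and DESeq2 called 5, all with positive differences. These were Slirp, Timm8b, Cox7b, Cox6c and LOC103694416, the last 2 named after their values were seen. Spinal cord genes had the largest list difference, with a median of -2.56 (camera preset, Down, adjusted p = 7.49e-12; adjusted p = 0.788 with an estimated correlation), and kept that call without each rat in turn. Rat B carried most of it, with a surgical minus control level of 4.80 against 0.32 in rat A and 0.83 in rat E, and without rats B, C and H the list had an adjusted p of 0.507. MHC class II and interferon genes had 24 of 24 positive with a median of 0.61 (Up, adjusted p = 9.81e-06; adjusted p = 0.788 with an estimated correlation), but 0.605 without rat B. Axon injury genes had a median of 0.01, which changed sign with the scaling, and a mean of 0.05 (Down, adjusted p = 0.984; adjusted p = 0.992 with an estimated correlation), so no difference between the times was detectable for them. In all, 2 lists were Up and 8 Down with the preset correlation, 0 with an estimated one and 0 by fry (smallest adjusted p = 0.898). Without rat B 8 calls were lost (adjusted p from 0.0711 to 0.728), without rat C 8 (0.0657 to 0.865), without rat E 3 (0.127 to 0.299) and without rat G 3 (0.0687 to 0.0844). Median and mean differed in sign for repair Schwann cell genes (0.31 and -0.06, Down). The simulated data gave recoveries of 0% at 2-fold and 2% at 4-fold, so this comparison could show only very large differences.

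Control ganglia were compared between 8 and 6 weeks to measure how the unoperated side differs with time, each time being represented by different rats. Ass1, the argininosuccinate synthase gene of arginine metabolism, was higher at 8 weeks, at 95.1 TPM (SD 9.43, n = 4) against 23.8 (SD 8.24, n = 3), a log2 difference of 1.42 (SE 0.16, adjusted p = 0.0344). Most of the genes that were lower encode small proteins of mitochondria, chromatin and transcription. The ATP synthase gene Atp5f1e was at 6910 TPM (SD 713, n = 4) against 15380 (SD 2408, n = 3), a log2 difference of -1.81 (SE 0.22, adjusted p = 0.0354). The ATP synthase genes Atp5mk (-1.79, SE 0.23) and Atp5mg (-1.37, SE 0.16) and the mitochondrial genes Mrps18c (-1.87, SE 0.20), Chchd1 (-1.47, SE 0.17) and Cox7b (-1.47, SE 0.17) were among them. So were Itgb3bp of the kinetochore (-1.69, SE 0.21), the transcription genes Med21 (-1.65, SE 0.19) and Polr2k (-1.57, SE 0.17), and the folding genes Fkbp3 (-1.63, SE 0.16) and Pfdn5 (-1.57, SE 0.19), all with adjusted p from 0.0344 to 0.0484. In total 25 of 16346 genes passed in edgeR, 3 higher (Ass1, Arxes1 and ENSRNOG00000064935, the last named after its values were seen) and 22 lower, and 5108 had an unadjusted p under 0.05. Arxes1 was at 0 counts in every 6-week control and at least 11.9-fold higher at 8 weeks, and ENSRNOG00000064935 at least 14.6-fold higher. LOC103690821, also named after its values were seen, was at 0 counts in every 8-week control and at least 113-fold higher at 6 weeks, each bound taken against 3 counts per library. DESeq2 called 3133 genes (1565 higher, 1568 lower), and limma on log2 TPM called 8 (4 higher, 4 lower) or 13 (7 higher, 6 lower) by the added constant, of which 3 were among the 25 in each case.

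In control ganglia the number of genes past the threshold depended on single rats, while the median difference of the genes called with all rats changed little. Leaving out rat A, B, D, C or G left 0 genes, leaving out rat H left 1, and leaving out rat E gave 6388. All 25 genes kept their sign in each of these fits, and the median of the 22 lower genes lay between -1.41 (without rat B) and -1.61 (without rat H). These genes were picked in a fit that held the same rats, which by itself favours a stable sign and size. Without rats A and B together the median was -1.24. Of the 22 lower genes 17 lay in the shortest 10% of transcripts (two-sided Fisher exact p = 9.18e-14 against 1535 of 15806 tested genes with a length). Genes of the same libraries are not independent replicates, so this p-value does not measure the spread between libraries. Between libraries the correlation with length had an exact permutation p of 0.0286 (adjusted p = 0.143). In the shortest 10% of transcripts, 75% of the genes were lower, with a median of -0.49 (SD 1.01), against 50.7% of the longer genes. After the trend with length was removed in each library, 0 genes passed (adjusted p from 0.0643 to 0.145 for the 25) and the median of the 22 moved from -1.57 (median SE 0.17) to -1.12 (median SE 0.16). With limma on log2 TPM it was -0.88 (median SE 0.17) or -0.93 (median SE 0.18) by the added constant, and 3 of the 25 passed with either. These were Arxes1, ENSRNOG00000064935 and LOC103690821, each at 0 counts in every control of 1 time. Ass1 and the named mitochondrial, transcription and folding genes were not among them. In the surgical ganglia 21 of these genes were tested and all 21 were lower at 8 weeks, with a median of -0.57 (median SE 0.24) and no adjusted p below 0.671. The TPM scale moved the median of all genes by 0.59 in this comparison, by 0.20 at 6 weeks, by -0.12 at 8 weeks, by -0.33 in the difference between the times and by 0.25 in the surgical ganglia below.

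**Figure D4:**
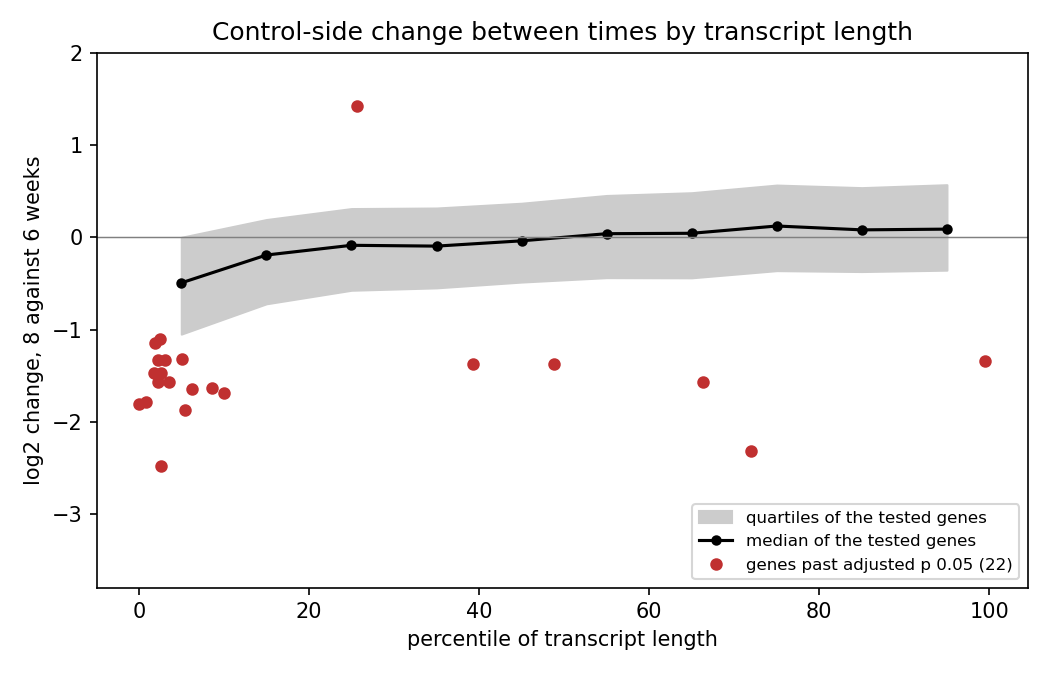
Log2 change in control ganglia between 8 and 6 weeks against the percentile of transcript length, with the median and quartiles of tested genes by bins and the 22 drawn genes past adjusted p 0.05 as points; 3 more lie beyond the axis. The shortest 10% of transcripts has a median of -0.49.

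Lists of neuronal genes lay higher and those of myelinating Schwann cells, immune cells and fibroblasts lower in control ganglia at 8 weeks by camera with the preset correlation, and none passed with an estimated one (smallest adjusted p = 0.459 with an estimated correlation). The neuronal marker level of these libraries was itself 9.05 (SD 0.25, n = 4) at 8 weeks and 8.13 (SD 0.81, n = 3) at 6 weeks, and with that level as a covariate, chosen after the data were seen, 11 lists passed instead of 19. Macrophage (adjusted p = 0.159), T, B and NK cell (0.965), immediate early (0.201), proprioceptor (0.846) and inhibitory receptor genes (0.403) were then among those that did not, neutrophil genes turned from Down to Up (0.0182) and muscle genes passed as Up (1.87e-05). The smallest value was then adjusted p = 0.414 with an estimated correlation. Voltage-gated sodium and calcium channels had 24 of 25 positive with a median of 1.13 (camera preset, Up, adjusted p = 1.22e-08), potassium channels 24 of 25 with 1.04 (3.58e-08), peptidergic nociceptor genes 14 of 15 with 1.11 (3.07e-06) and non-peptidergic nociceptor genes 13 of 15 with 1.04 (3.61e-06). Myelinating Schwann cell genes had 16 of 16 negative with a median of -0.996 (Down, adjusted p = 1.81e-10), macrophage genes 22 of 22 with -1.34 (1.42e-07), inflammatory cytokines 18 of 19 with -1.56 (3.2e-07), MHC class II and interferon genes 22 of 24 with -1.05 (3.2e-07), fibroblast genes 20 of 21 with -0.86 (5.2e-06) and immediate early genes 18 of 18 with -1.29 (1.16e-05). These 10 lists had adjusted p = 0.459 with an estimated correlation, as the smallest of this comparison, and in all 8 lists were Up and 11 Down with the preset one. fry called 0 one way (smallest adjusted p = 0.0951) and 4 in either direction. Adjusted over the list alone, 15 of 16 myelinating Schwann cell genes were lower, among them Mbp (-1.71, SE 0.28) and Ncmap (-1.20, SE 0.20), as were 18 of 24 MHC class II and interferon genes, 10 immediate early, 9 macrophage, 9 cytokine, 5 T, B and NK cell and 5 fibroblast genes. Adjusted over the list alone, 9 non-peptidergic genes were higher and 1 lower, 5 cold receptor genes higher and 1 lower, and 3 potassium channel genes (Kcnd3, Kcnc4 and Kcnk3), 3 sodium and calcium channel genes (Scn11a, Scn3b and Cacna2d2), 2 peptidergic genes (Kit and Oprm1) and 1 inhibitory receptor gene (Oprm1) higher. The neurotrophic factor gene Cntf and the spinal cord gene Gad1 were lower and Slc5a7 of the spinal cord list higher by the same adjustment. None of these list members passed over all genes tested, of which 5108 of 16346 had an unadjusted p under 0.05. Counts adjusted over a list alone therefore do not show by themselves a change particular to that list. The neutrophil (adjusted p = 0.0307), red blood cell (0.0356), circadian clock (0.0388) and glucocorticoid response calls (0.0152) were each lost without at least 1 rat, all 4 of them without rat A (0.0812 to 0.174). Skeletal muscle genes had a median of 4.43 (Up, adjusted p = 0.0779, adjusted p = 0.735 with an estimated correlation). This median rested on the control library of rat H, whose level was 8.33, against 0.96 to 1.68 in the other 3 at 8 weeks. Without rat H the list turned to Down and passed with the preset correlation. No value with an estimated correlation is given for that fit. Axon injury genes had a median of -0.07 and a mean of 0.03 (Up, adjusted p = 0.527; adjusted p = 0.653 with an estimated correlation), and their median changed sign once the length trend was removed (0.18 relative to all genes). The satellite glia median (-0.06) and the adipocyte median (0.57) changed sign relative to all genes on the TPM scale.

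The surgical ganglia were compared between the times in the same way. Gatm, the creatine synthesis gene, averaged 21 TPM (SD 4.98, n = 4) at 8 weeks and 38.8 TPM (SD 6.39, n = 3) at 6 weeks, a log2 difference of -1.21 (SE 0.24). Sox9, a glial transcription factor gene, stood at -1.82 (SE 0.37) and the natriuretic peptide gene Nppc at -2.33 (SE 0.49). On the higher side were the pseudogene Vdac1-ps11 (2.36, SE 0.39), Cnbd2, a cyclic nucleotide binding gene (0.91, SE 0.21), and the receptor gene Gprc5c (0.91, SE 0.22). None passed (adjusted p = 0.671, edgeR, n = 4 against 3): 0 of 16606 genes did and 1089 had an unadjusted p under 0.05. DESeq2 called 8 (6 higher, 2 lower), namely Vdac1-ps11, Cnbd2, Hhipl1, Ufsp1, ENSRNOG00000063421 and ENSRNOG00000064310 higher and Gatm and Sox9 lower. limma on log2 TPM called 3 (1 higher, 2 lower) or 4 (2 higher, 2 lower) by the added constant, the higher ones being LOC120101375 and, with the smaller constant, AABR07055864.2, and the lower ones AY172581.21 and Metazoa_SRP (ENSRNOG00000051566). Hhipl1, Ufsp1, the genes without a symbol and those called by limma are named after their values were seen. Spinal cord genes had 13 of 13 negative with a median of -5.16 (camera preset, Down, adjusted p = 9.42e-08; adjusted p = 0.67 with an estimated correlation), with Mog at -6.05 (SE 1.60) and 11 genes lower adjusted over the list alone. Rat B's library at 6 weeks had the highest level of these genes, and the call with the preset correlation was kept without rat B. An estimated correlation was not run there. Myelinating Schwann cell genes had 16 of 16 negative with a median of -1.17 (Down, adjusted p = 5.59e-11), and 1 of them, Cnp (-1.09, SE 0.25), was lower adjusted over the list alone. Both lists had adjusted p = 0.67 with an estimated correlation, as the smallest of this comparison, and in all 5 lists were Up and 11 Down with the preset correlation, 0 with an estimated one and 0 by fry (smallest adjusted p = 0.597). Without rat A 10 of these calls were lost (adjusted p from 0.0941 to 0.98), those of the neuronal lists among them: potassium channels had an adjusted p of 0.000153 with all rats and 0.472 without it. Without rat G 2 calls were lost (0.0515 and 0.0669), without rat D 1 (0.153) and without rat H 1 (0.167). Median and mean differed in sign for axon injury genes (-0.03 and 0.13, Up) and cold receptor genes (0.09 and -0.03, Up), and the test differed from both for adipocyte genes (0.18 and 0.11, Down). The simulated data gave recoveries of 0% at 2-fold and 22% at 4-fold.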

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

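All tests of explanations below were chosen only after the results were seen. Values were marked by a rule for a single rat apart from its group or for a list whose surgical change differed between the times; the first rule marked 7 of 60 groups, where about 3 would be marked by chance.

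Axon injury genes had a mean log2 difference of 0.453 (SE 0.154 over 30 genes) on the surgical side over both times. This SE and those of the means below were taken over genes. Such genes share the same rats and are not independent replicates, so these SEs do not measure the spread between rats. With the neuronal marker level as a covariate the mean was 0.532 (SE 0.173), so neuronal content of the libraries, as these markers measure it, does not account for the mean. Without rat B, whose surgical library held spinal cord transcripts, the mean was 0.481 (SE 0.17), so that tissue does not account for the mean. The list without rat B did not pass camera with an estimated correlation (adjusted p = 0.646), and neither did it with all rats (0.703). A response of sensory neurons to the operation remains open: the list level differed by 0.416 (SD 0.445) over 7 rats, with an exact two-sided sign flip p = 0.0625.

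Skeletal muscle genes were high in the surgical libraries of rats C and E and the control library of rat H. Muscle tissue carried in at dissection is a candidate explanation in rats C and H, where all 11 tested muscle genes outside the list stood 3 or more log2 units above their median in the other libraries; these genes do not tell by which route muscle RNA entered. In rat E only 5 of the 11 did, which met the first bound set against carried-in muscle; that bound was given up after it was seen, because all 11 lay above that median, and the source there stays open. In rat H the surgical side stood at -6.58 relative to the control, which excludes the graft there if the side labels of rat H are right, and the correlation of its libraries (-0.308) does not settle them. For rats C and E the graft stays open, since the sign flip test over all 7 rats (exact p = 0.594) does not bear on 2 libraries.

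In control ganglia 22 genes were lower at 8 weeks, with a median of -1.57 (median SE 0.173). The median was -1.12 (median SE 0.163) after the length trend was removed, and 0 genes then passed, for a reason that was not tested, so the trend stays open as a cause. With the neuronal marker level as a covariate the median was -1.27 (median SE 0.16) and 10 of the 25 genes still passed, so a linear term for these markers did not remove the difference. The genes were picked in the same libraries, and the level itself stood at 9.05 at 8 weeks and 8.13 at 6 weeks. This fit therefore cannot exclude neuronal content as the cause. The passing of time, shared by both sides, would by itself give similar levels on both sides of a rat. At 6 weeks the 22 genes averaged a log2 CPM of 6.75 in the control and 4.87 in the surgical library of rat B. They averaged 6.29 and 5.22 in rat E and 6.52 and 5.82 in rat A. These values argue against time as the whole cause, though picking the genes on the control side favours such a gap. A part shared by both sides remains open: on the surgical side the median of the same genes was -0.573 (median SE 0.236), and none passed there.

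Of other single values, spinal cord genes differed between the sides by 4.797 in rat B. In rat C the differences were -1.227 for Gal, 1.422 for Csf1, 2.855 for Pvalb and 3.515 for Cd68. The level of the skeletal muscle list differed by 8.705 in that rat. The proprioceptor list, which holds Pvalb, differed by -0.713 there, and the macrophage list, which holds Cd68, by 1.869. Whether tissue content accounts for these single values was not tested. The muscle level of rat H stood at 8.328 among 8-week controls, and the neuronal level of rat C at 8.143 among 8-week surgical libraries. The surgical change differed between the times by camera with the preset correlation for peptidergic nociceptor genes (adjusted p = 0.0394), non-peptidergic nociceptor genes (0.00256), cold receptor genes (0.0394), potassium channels (0.00256), sodium and calcium channels (8.7e-05), inhibitory receptors (0.00556), macrophage genes (0.00556), MHC class II and interferon genes (9.81e-06), spinal cord genes (7.49e-12) and cholesterol synthesis genes (0.00027). All 10 of these had adjusted p = 0.788 with an estimated correlation.

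Splits of the libraries, the real one among them, were run for each count of genes. Where the real count is 0 every split reaches it, so 100 of 100 splits over both times, 32 of 32 at 8 weeks, 35 of 35 for the difference between the times and 35 of 35 in surgical ganglia decide nothing about chance. The highest other count was 15 over both times, in a split that kept both libraries of some rats together, and 1 among the 64 splits that part every pair as the real one does. It was 0 at 8 weeks and 0 for the difference. At 6 weeks all 10 of 10 splits called 0, and the splits are too few. In control ganglia 2 of 35 splits, the real one included, called at least the real 25, and the highest other count was 361 for rats A, B, D and H against C, E and G, so chance cannot be excluded. In surgical ganglia the highest other count was 2301 for rats D, E, G and H against A, B and C. The last 3 are the surgical libraries with the lowest neuronal levels, 6.624, 8.542 and 8.143, and the only surgical ones below 0 on the first principal component. Such a count points to a structure of the samples, which was not tested.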

How the results depend on the processing

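The removal of rats, the neuronal covariate and the length trend were chosen only after the data were seen, and the other settings beforehand. For each moved count the cause was not tested.

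With DESeq2 the counts of genes moved from 0 to 6 over both times, to 44 at 6 weeks, to 4 at 8 weeks and to 5 for the difference between the times, from 25 to 3133 on the control side, and from 0 to 8 on the surgical side. With limma on log2 TPM the control side moved from 25 to 8 with 1 added and to 13 with 0.1 added, and the surgical side from 0 to 3 and 4. Without the replicate block the count at 6 weeks moved from 0 to 2.

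On the control side 25 genes moved to 0 without rats A and B, to 15 with the neuronal covariate and to 0 with the length trend removed. Leaving out 1 rat moved this count to between 0 and 6388, the highest without rat E, and left the other counts at 0.

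The lists called with the preset correlation numbered 9 over both times, 6 at 6 weeks, 15 at 8 weeks, 10 for the difference, 19 on the control side and 16 on the surgical side. With an estimated correlation each of the 6 moved to 0, and with fry each of the 6 moved to 0. Without rats B, C and H the lists moved to 18 over both times, to 14 at 6 weeks and to 6 for the difference. With the neuronal covariate they moved to 11 at 6 weeks, 9 at 8 weeks, 11 on the control side and 6 on the surgical side. With that covariate 1 list passed with an estimated correlation, axon injury over both times (adjusted p = 0.0292). By fry it passed too (0.0151), as did potassium channels at 6 weeks (0.0202) and for the difference (0.0239).

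No named gene that passed changed sign in any setting. All such genes are from the control side and were picked in the same libraries, which by itself favours a stable sign. Counted by gene and setting, their calls were lost 148 times over 17 settings.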

Other observations

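The measures below were looked at only after the results were seen.

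The 22 genes lower at 8 weeks on the control side also differed between the sides of single rats at 6 weeks. Their mean log2 CPM was 6.75 in the control and 4.87 in the surgical library of rat B, and 6.29 and 5.22 in rat E, while all 8-week libraries lay between 4.38 and 4.77. In rat A both libraries stood high, at 6.52 and 5.82. LOC103690821 had 289 and 178 counts in rat A, 272 in the control library of rat B and 286 in that of rat E, and 0 counts in the surgical libraries of rats B and E and in all 8-week libraries. A factor shared by some libraries rather than by a time could therefore contribute. Time shared by both sides is not the whole cause by these values, and the median on the surgical side of -0.573 leaves a part for it open.

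The list level difference of the axon injury genes was negative in rats A and C (-0.103 and -0.19) and highest in rats B and H (0.932 and 0.936). The surgical libraries of rats A and C had the lowest neuronal level of their groups, which could lower these values, and the mean of the list with the neuronal covariate was 0.532 against 0.453 without it.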
